A study of Pyronema omphalodes CBS 100304 with 9 samples.

How the data were processed

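Gene expression was measured by RNA sequencing in 9 libraries of the ascomycete Pyronema omphalodes (Pyronema confluens). Per the labels' protocols, protoapothecia grew for 4 d at 25 °C on slides carrying 150 µl of WPC medium with 0.8% agar, were fixed in ethanol in the cold and were cut out with a laser. Their total RNA was amplified linearly before library preparation with Illumina chemistry. The series' design text names 3 independent biological replicates of protoapothecia and adds reads from an earlier study of mycelium. Per the labels' protocols, mycelium RNA was extracted in bulk. Sexual mycelium grew as surface culture in constant light and vegetative mycelium as surface culture in constant darkness, each pooled from days 3, 4 and 5. The vegetative pool combined submerged cultures in light and in darkness with a dark surface culture on a minimal medium, after 3 d. The light condition of the protoapothecium slides is not stated. Each sample was put in its group by its title or description, and each column of the deposited table was matched to a sample by its name.

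The authors deposited 1 table of the whole series. It gives raw read counts per gene model for each library, per the file headers, with no normalization. It also gives, per the file headers, the authors' consensus calls for each comparison as a score of −1, 0 or 1, and gene model lengths. Base calling used CASAVA 1.8.2 and the notes also name DESeq, without a version, per the submitters' processing notes. The aligner, the counting tool, the genome build and whether counting used strand are not given in the sources used here. Positions are scaffold coordinates of the deposited table. The reference table of locus tags was not used here. Gene names are the product descriptions of the deposited table, which rest on similarity to proteins of other organisms, so a name does not establish function in this fungus. Of 13369 genes, 5564 had no described product. Among the genes tested, 393 overlapped another gene. Their counts are uncertain without strand, and genes with overlaps are not named in the text. There were 0 columns of per-sample values outside the 9 libraries.

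Total counts ranged from 5583951 (protoapothecia B) to 24803660 (protoapothecia C), and the other 8 libraries had at least 14265890. A level of 3 counts, the floor used for genes at 0, is worth 0.642 CPM in protoapothecia B and 0.112 to 0.202 CPM in the other libraries. Fold changes against a group with no counts are lower bounds at a floor of 3 counts over the group. Where the lower group had 1 to 3 counts, levels are given and no fold. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

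Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passed filterByExpr (minimum count 10, minimum total 15), which left 11787. Libraries were scaled by TMM, dispersions were estimated over 4 groups in 1 fit that shared the estimate of spread (5 residual degrees of freedom), and each of 6 comparisons was tested with the robust quasi-likelihood test (glmQLFTest), two-sided. P-values were adjusted by Benjamini-Hochberg over all genes tested, and every "edgeR adjusted p" is of this kind. The threshold was 0.05. Log2 CPM for principal components used a prior count of 2. No block for the replicate number was used, since nothing in the labels says that numbers pair the mycelium samples.

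A set of 32 gene lists was fixed as patterns on the product descriptions. Matches naming another protein were left out after reading the descriptions alone: 4 of 9 for mating, 2 of 11 for regulators, 1 of 19 for MAP kinase, 4 of 105 for DNA replication, 4 of 23 for glycolysis, 17 of 35 for the citrate cycle, 10 of 61 for plant cell wall degradation, 9 of 55 for chitin and glucan, 5 of 101 for transport, 6 of 41 for proteases, 8 of 72 for chaperones, 16 of 99 for the cytoskeleton and 3 of 19 for transposons. A list of mitochondrially encoded or rRNA-like features lost 12 of 12 matches and could not be used. Of the 31 lists with members, 30 had at least 5 tested genes and were tested with limma's camera, which asks whether a list moved more than the other genes. The preset correlation between genes was 0.01, with Benjamini-Hochberg adjustment within each comparison ("camera adjusted p"). The test was repeated with the correlation estimated per list and with fry, which asks whether a list's genes move one way without comparing them with other genes. Members were counted as higher or lower at adjusted p below 0.05 over all genes and when adjusted over the list alone. In the called lists, a member with no counts in one group lies on the same side of the list's median at its bound as at its fitted value, so the median stays as given.

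Genes were named by a rule. It took genes at adjusted p below 0.05 whose CPM did not overlap between the groups, with a mean of at least 10 CPM in the higher group and a description naming a protein or function. Of these, the 8 largest rises and 8 largest falls could be named for the main comparisons, and 4 and 4 for protoapothecia against the vegetative groups and between those groups. It added up to 3 members with the smallest adjusted p per list, and any member of the mating, regulator, NADPH oxidase and STRIPAK, light sensing and carotenoid lists. Groups, comparisons, the tests of genes and lists, the lists, the alternatives and this rule were chosen before the data were examined. The tests of neighbours, domains, set properties, length trends and a fixed share of protoapothecium RNA were chosen later. After values were seen, 2 genes whose descriptions name no function were set aside. Genes named for their abundance, and examples of genes shared between comparisons, were chosen after their values were seen.

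Overlap of calls was set beside the overlap of independent lists (n1 × n2 / N). Where comparisons shared a group, it was also set beside 20 simulations in which all 4 groups had the same means. Lists matched on mRNA length and mean expression were drawn 10000 times from 5 classes of each. Sets of genes were compared with sets of other genes matched on mean expression alone. Neighbouring genes were counted in 1000 permutations of gene placement, also for pairs at least 1000 bases apart. Protein domains with at least 5 genes were tested for enrichment with a one-sided Fisher's exact test and Benjamini-Hochberg adjustment. The background was all tested genes with a domain, without matching.

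The procedure was tested on simulated counts drawn from the real means and library sizes. For protoapothecia against sexual mycelium (11588 genes), it recovered 41% of genes changed 4-fold and 5% of those changed 2-fold, with 2.13% of calls false. For sexual against vegetative mycelium (11618 genes) it recovered 43% and 0%, with 6.52% false, and between the vegetative groups (11593 genes) 53% and 2.02%, with 11.3% false. A gene not past the test is therefore not shown to be unchanged. The simulations changed only 99 or 100 tested genes per fold, fewer than were called in the data. This makes the adjusted threshold stricter, so recovery in the data may be higher than simulated. Alternatives were RLE and upper-quartile scaling, no filter, a filter of 50 counts in 2 libraries, DESeq2 1.42.0, a fit with only the compared groups, adjusted p below 0.01, a test against a fold change of 2, a replicate block, thinning to the smallest library, and leaving out each library in turn.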

Results

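RNA sequencing measured transcript levels in Pyronema omphalodes (also called Pyronema confluens), a soil ascomycete that forms small disc-shaped fruiting bodies called apothecia. There were 9 libraries in 4 groups. Protoapothecia, the young fruiting bodies, were cut out by laser microdissection in 3 independent biological replicates, A, B and C. They came from cultures grown for 4 d at 25 °C on slides carrying 150 µl of agar medium. The other groups held 2 libraries each and were read in an earlier study: sexual mycelium (surface culture in constant light, days 3, 4 and 5 pooled), vegetative mycelium (surface culture in constant darkness, days 3, 4 and 5 pooled) and a vegetative pool (submerged cultures in light and in darkness plus a dark surface culture on another medium, 3 d). Counts summed to 24494613, 5583951 and 24803660 in protoapothecia A, B and C. They summed to 17221767 and 22132904 in sexual mycelium 1 and 2, 14265890 and 14835205 in vegetative mycelium 1 and 2, and 19887119 and 14473365 in vegetative pool 1 and 2. Levels are in CPM (each library's counts scaled to a common total, with TMM factors), given as mean ± SD with n = 3 for protoapothecia and n = 2 for each mycelium group.

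Protoapothecia had the most uneven transcript pool. Their 10 most abundant genes took 11.8% of the counts in A, 13.4% in B and 9.99% in C, against 6.88% to 9.58% in the mycelia. The most abundant protoapothecium gene, chosen after its values were seen, was PCON_12394, described as L-tyrosine decarboxylase, an enzyme that turns tyrosine into tyramine. It reached 33520 ± 5320 CPM in protoapothecia and 4468 ± 726 in sexual mycelium. Next among genes with a described product were the fucose-specific lectin PCON_04233 (13810 ± 3430), the proline permease PCON_08572 (12030 ± 4430) and leucine aminopeptidase 2 PCON_11583 (9831 ± 3670). In each mycelium group the leading gene was elongation factor 1-alpha PCON_04930, a translation factor (14280 ± 16, 17840 ± 1590 and 15440 ± 1020 CPM in sexual, vegetative and pooled mycelium). Sexual mycelium showed the widest range of transcripts. After thinning each library to 5583951 counts, 12564 and 12389 genes had at least 1 count in sexual mycelium, 11754, 11323 and 11706 in protoapothecia, and 10989 to 11481 in the vegetative libraries.

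**Figure D1:**
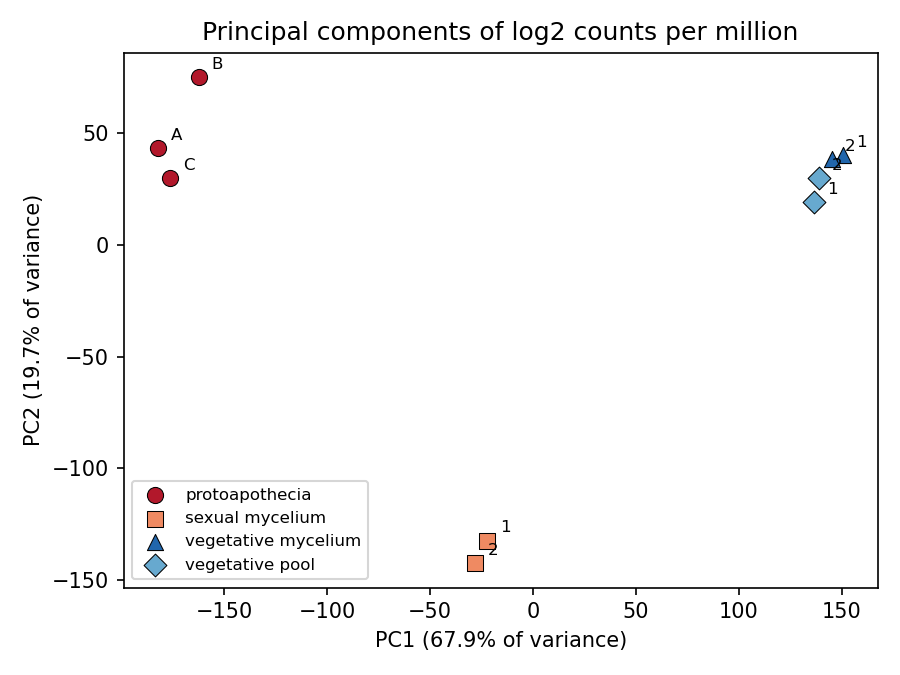
Principal components of log2 CPM over 11787 genes, 1 point per library, with PC1 (67.9% of the variance) on the horizontal axis and PC2 (19.7%) on the vertical axis. Protoapothecia lie between −182.1 and −162.3 on PC1, sexual mycelium at −28.2 and −22.2, and the 4 vegetative libraries between 136.5 and 150.6.

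The libraries fell into their labelled groups. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.939 to 0.959 within protoapothecia, 0.978 within sexual mycelium, 0.985 within vegetative mycelium and 0.981 within the pool. Between groups it was 0.707 to 0.740 for protoapothecia with sexual mycelium, 0.576 to 0.646 for protoapothecia with the vegetative groups, and 0.941 to 0.956 for vegetative mycelium with the pool. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 23.6. Protoapothecium RNA was taken from dissected, ethanol-fixed tissue and amplified, and mycelium RNA was extracted in bulk in an earlier study, so preparation and group cannot be told apart in any comparison with protoapothecia. Each mycelium library is labelled as one of a pair of technical replicates, and nothing says whether libraries 1 and 2 of a group came from separate cultures. P-values between mycelium groups therefore rest partly on the spread between these libraries, which may be technical. Through the shared fit they rest partly on the spread between protoapothecium replicates too. Comparisons with protoapothecia use the same estimate of spread. The mycelium pairs gave 3 of its 5 residual degrees of freedom, so those p-values also rest partly on a possibly technical spread. Each mycelium group may stand for a single culture.

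**Figure D2:**
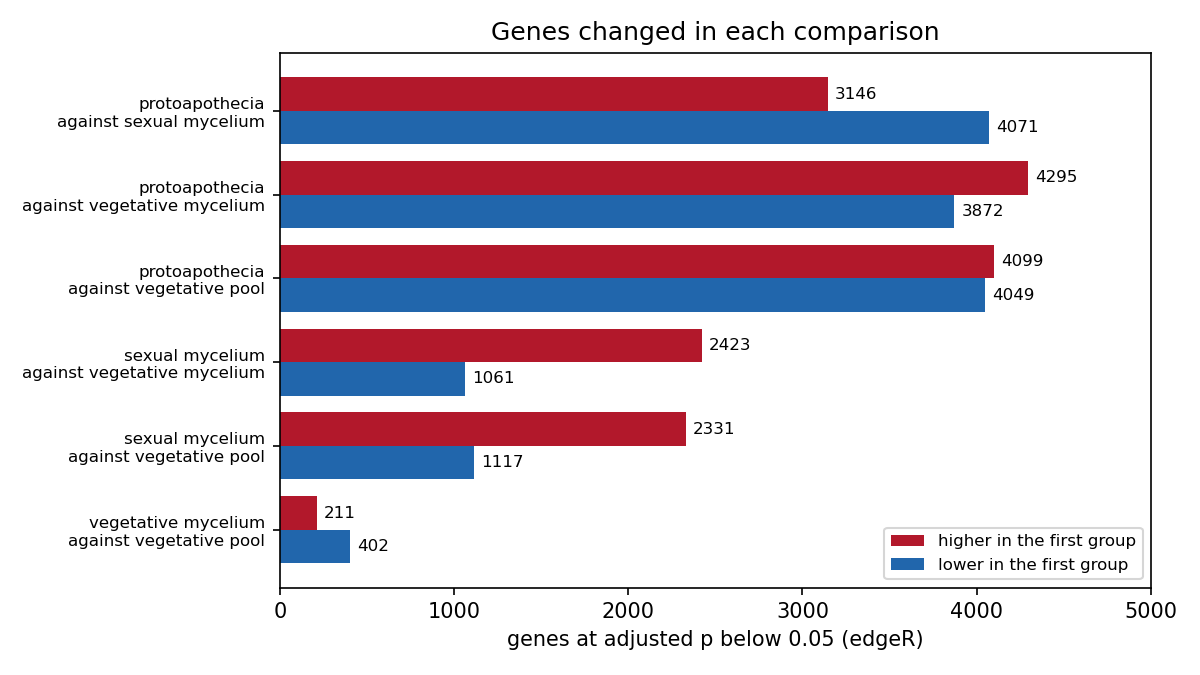
Number of genes at edgeR adjusted p below 0.05 in each comparison (horizontal axis, genes out of 11787 tested), split into genes higher (red) and lower (blue) in the group named first. The bars run from 7217 genes in total for protoapothecia against sexual mycelium and 8167 against vegetative mycelium to 613 between the vegetative groups.

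Protoapothecia against sexual mycelium addressed how young fruiting bodies differ from the sexually developing mycelium as a whole. Benzoate 4-monooxygenase PCON_08024, a cytochrome P450 that hydroxylates benzoate, reached 3938 ± 905 CPM against 30.3 ± 1.24 (log2 fold change 7.02, SE 0.617, edgeR adjusted p = 1.79e-05); its gene lies on scaffold 365 from 69134 to 71341, plus strand. Leucine aminopeptidase 2 PCON_11583, which removes N-terminal residues from peptides, reached 9831 ± 3670 against 196.5 ± 11.6, and AlcS PCON_11585 4259 ± 1010 against 60.9 ± 12.1 (5.64 and 6.13, edgeR adjusted p = 9.1e-06 and 1.35e-05). These genes lie close together on scaffold 615, from 33162 to 35473 (plus strand) and from 38091 to 39219 (minus strand). Cutinase PCON_11410, which splits plant cuticle esters, rose from 4.64 ± 0.386 to 298.4 ± 173 CPM, and rhamnogalacturonan acetylesterase PCON_10535, which acts on pectin, from 4.49 ± 0.57 to 248.9 ± 77. Other large rises were phospholipase A2-gamma PCON_03771 (6.29), oleic acid lipoxygenase PCON_08404 (5.50) and quinidine resistance protein 3 PCON_07867 (5.49).

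Among single genes lower in protoapothecia than in sexual mycelium, glycogenin-2 PCON_04451, which primes glycogen synthesis, fell by 8.35 on the log2 scale to 0.386 ± 0.15 CPM from 143.9 ± 23.8 (edgeR adjusted p = 3.6e-06). The cell wall mannoprotein PIR3 PCON_03885 fell by 8.13 and a subtilisin-like serine protease PCON_13506 fell by 7.38, the latter to 3.05 ± 1.82 from 466.6 ± 74.5 CPM. Conidiation-specific protein 6 PCON_11571, named for a gene expressed during asexual sporulation in Neurospora, had 3 counts over the protoapothecium libraries against 15.2 ± 4.14 CPM (edgeR adjusted p = 7.29e-06). Formin-binding protein 4 PCON_02356 also had 3 counts, against 36.1 ± 2.44 CPM. An ankyrin repeat protein, PCON_09184, had no counts in protoapothecia and was at least 187-fold lower than the 12.5 ± 5.23 CPM of sexual mycelium, with the floor set at 3 counts over the group. Of 11787 genes tested, 3146 were higher and 4071 lower at adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1979 and 2855 passed a test against a fold change of 2. The split was 3520 and 3749 with RLE scaling and 3682 and 3728 by DESeq2. The median log2 change of all genes was −0.139, and it was 0.0337 with RLE in place of TMM scaling, so the medians beside list tests are given relative to the median of all genes. Medians in the plot of gene lists, in the comparison of signs and in tests against matched lists are not shifted in this way.

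**Figure D3:**
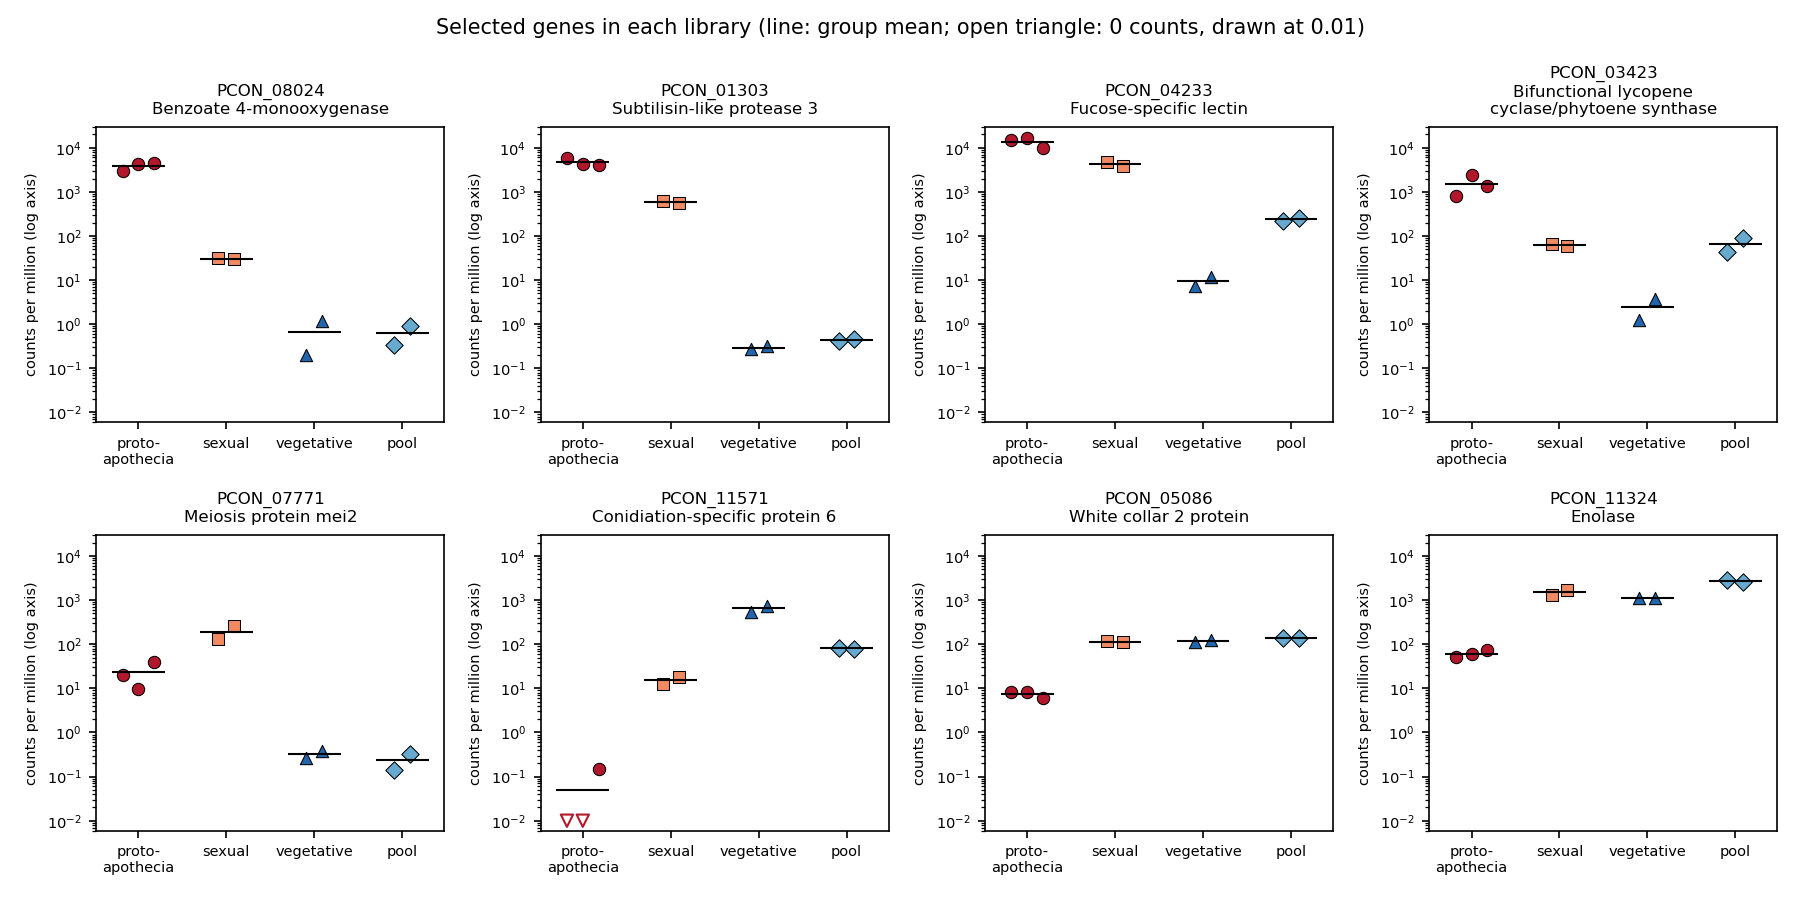
CPM of 8 genes in each library (vertical log axis), grouped by sample group on the horizontal axis, with the line at the group mean and open triangles for 0 counts drawn at 0.01. Benzoate 4-monooxygenase, subtilisin-like protease 3, the lectin and lycopene cyclase/phytoene synthase were highest in protoapothecia, mei2 in sexual mycelium (193 ± 84.5 CPM) and conidiation-specific protein 6 in vegetative mycelium (652 ± 141), and white collar 2 and enolase were lowest in protoapothecia.

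Light sensing genes fell in 5 of 5 members in protoapothecia relative to sexual mycelium (median −2.45, camera adjusted p = 0.00187, adjusted p = 0.174 with an estimated correlation). The list lay at percentile 2.89 of lists matched on length and expression, inside their central 95%. White collar 2 PCON_05086, a subunit of the fungal blue-light receptor complex, fell by 3.91 on the log2 scale (SE 0.214), to 7.63 from 114.3 ± 1.93 CPM (edgeR adjusted p = 3.6e-06; scaffold 192, 9619 to 11710, plus strand). The clock protein frequency PCON_09365 fell by 3.47, white collar 1 PCON_03119 fell by 2.59, cryptochrome DASH PCON_04123 fell by 2.24 and a phytochrome PCON_06747 fell by 1.94. The labels give the light condition of the sexual mycelium and not of the protoapothecia. Carotenoid synthesis was split, with 2 of 3 members higher and 1 lower. Lycopene cyclase/phytoene synthase PCON_03423 and phytoene dehydrogenase PCON_03421, consecutive steps towards coloured carotenoids, rose to 1536 ± 831 and 1299 ± 348 CPM (4.63 and 2.04, edgeR adjusted p = 0.000287 and 0.00304). Geranylgeranyl diphosphate synthase PCON_05718, which makes their precursor, fell by 2.74 to 9.56 ± 2.97 CPM. Counts adjusted over the list alone equalled those over all genes tested for both lists.

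Members of the mating and developmental lists went both ways between protoapothecia and sexual mycelium. Of 5 mating type and pheromone genes, 1 was higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.859). A receptor for the alpha pheromone, PCON_02097, rose from 2.71 ± 0.44 to 33.3 ± 12.9 CPM (3.62, edgeR adjusted p = 0.00126), and the mating-type gene MAT1-1-1 PCON_07491 stood at 140 ± 48.4 against 105 ± 19.9 (0.42, edgeR adjusted p = 0.232). In a list of 9 genes fixed by names of developmental regulators and fruiting-body proteins, 3 were higher and 3 lower, again also over the list alone (camera adjusted p = 0.881). Its members include regulators of conidiation. WetA PCON_02676, named for an Aspergillus regulator of conidium maturation and not of fruiting bodies, rose from 64.2 ± 3.46 to 1202 ± 46.4 CPM (4.23, edgeR adjusted p = 4.02e-06). SteA PCON_01154, named for an Aspergillus factor required for sexual development, fell by 2.78 to 6.44 ± 2.28 CPM, and the secreted protein SC7 PCON_04524 fell by 6.28. Of 5 NADPH oxidase and STRIPAK genes 1 was higher and 1 lower, also over the list alone (camera adjusted p = 0.836). The striatin Pro11 PCON_13421, whose Sordaria namesake is needed for fruiting-body maturation, rose from 94.4 ± 0.474 to 287.9 ± 74.8 CPM (1.61, edgeR adjusted p = 0.000427), and an NADPH oxidase PCON_03267, which makes superoxide, fell by 1.73 to 2.27 ± 1.24 CPM.

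The lists of cytosolic ribosomal proteins, glycolysis, the citrate cycle and chaperones were called lower in protoapothecia than in sexual mycelium. Cytosolic ribosomal proteins fell in 66 of 86 tested members, and in 67 adjusted over the list alone, with none higher (median −1.09, camera adjusted p = 1.25e-07, adjusted p = 0.297 with an estimated correlation). Examples were ribosomal protein L30 PCON_09052 (27.3 ± 1.58 against 320.1 ± 78.1 CPM) and S22 PCON_06603 (51.4 ± 3.25 against 274.2 ± 27.7). Glycolysis fell in 13 of 19 members and rose in 2, the same over the list alone (median −1.44, camera adjusted p = 0.00188, adjusted p = 0.297 with an estimated correlation). Enolase PCON_11324 fell by 4.66, to 60.9 ± 10.6 from 1538 ± 278 CPM, and pyruvate kinase PCON_04428 fell by 2.98 (edgeR adjusted p = 3.6e-06 and 5.51e-06). The citrate and glyoxylate cycles fell in 13 of 18 members, 15 adjusted over the list alone, and rose in 1 (median −1.48, camera adjusted p = 0.00231, adjusted p = 0.297 with an estimated correlation). Isocitrate lyase PCON_11839, the entry to the glyoxylate cycle, fell by 3.62 and citrate synthase PCON_01260 fell by 2.77. Heat shock proteins and chaperones fell in 37 of 61 and rose in 9, also over the list alone (median −0.928, camera adjusted p = 0.00366, adjusted p = 0.297 with an estimated correlation). Hsp70 PCON_06550 fell to 181.4 ± 50 from 3810 ± 203 CPM and Hsp90 PCON_11855 to 264.6 ± 31.8 from 3299 ± 213.

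Camera also called the incompatibility and RNA silencing lists lower in protoapothecia than in sexual mycelium, and the P450 and histone lists higher. Heterokaryon incompatibility and NACHT proteins, which in other fungi take part in non-self recognition between strains, fell in 17 of 20 members and rose in 1 (median −2.99, camera adjusted p = 0.00187, adjusted p = 0.174 with an estimated correlation). HET-E PCON_08266 fell by 4.99, to 1.21 ± 0.285 from 38 ± 6.44 CPM (edgeR adjusted p = 4.02e-06). RNA silencing fell in 5 of 11, with none higher and 6 not past the test (median −0.968, camera adjusted p = 0.0189, adjusted p = 0.297 with an estimated correlation). Dicer PCON_07058, which cleaves double-stranded RNA, fell by 3.86, and an RNA-dependent RNA polymerase PCON_07520, which makes it, fell by 4.19. The RNA silencing list lay at percentile 8.7 of matched lists, inside their central 95%. Cytochrome P450 genes, oxygenases of secondary and fatty acid metabolism, rose in 19 of 30 and fell in 4 (median 1.56, camera adjusted p = 0.00187, adjusted p = 0.174 with an estimated correlation). PCON_06415 among them rose from 119.8 ± 10 to 5238 ± 204 CPM (5.45, edgeR adjusted p = 3.6e-06). Histones rose in 7 of 9, with none lower (median 1.34, camera adjusted p = 0.0111, adjusted p = 0.297 with an estimated correlation), H2A.Z PCON_13456 from 93.8 ± 0.997 to 723.1 ± 38.3 CPM, and the list lay at percentile 94.5, also inside that range. Counts adjusted over the list alone were equal for these lists.

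The list of proteasome and ubiquitin ligase genes fell in 56 of 100 members, 58 adjusted over the list alone, and rose in 19 (median −0.789, camera adjusted p = 0.0197, adjusted p = 0.297 with an estimated correlation). Its members with the smallest p were ubiquitin ligases, which tag proteins, and not proteasome subunits. RNF167 PCON_02920 fell by 4.61 and RNF216 PCON_04197 fell by 3.87, and Slx8 PCON_03709 rose from 13.4 ± 0.354 to 150.9 ± 8.15 CPM (3.50, edgeR adjusted p = 3.68e-06). Cytoskeleton and motor proteins fell in 41 of 82 and rose in 15 (camera adjusted p = 0.0576), and myosin-2 PCON_11606 fell by 5.53 to 7.21 ± 3.35 CPM. Meiosis genes were lower in 18 of 43 and higher in 10, or 11 adjusted over the list alone (camera adjusted p = 0.341). The member with the smallest p was a negative regulator of sexual conjugation and meiosis, PCON_01122, which fell by 4.24 to 23 ± 3.31 from 434.5 ± 19.2 CPM and whose name is of a repressor of the process.

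The remaining lists were not called between protoapothecia and sexual mycelium. Where no count over the list alone is given, here and for later comparisons, it equalled that over all genes tested. Polyketide synthesis and melanin had 8 higher and 4 lower of 18 (camera adjusted p = 0.135), with polyketide synthase PCON_10055 rising from 61.5 ± 19.3 to 2299 ± 417 CPM and the tyrosinase PCON_04953 from 5.07 ± 2.22 to 62.8 ± 17.8. Plant cell wall degradation had 18 higher and 8 lower of 49, and lectins 5 higher and 1 lower of 11 (2 lower adjusted over the list alone), both at camera adjusted p = 0.135. A lectin PCON_12683 rose from 302.9 ± 72.2 to 4656 ± 2150 CPM. Chitin and glucan enzymes had 14 higher and 15 lower of 46 (camera adjusted p = 0.859), and chitin synthase G PCON_05667 fell by 4.89 (edgeR adjusted p = 3.68e-06), to 8.28 ± 0.532 from 245 ± 102 CPM. Beta-oxidation and peroxisome genes were higher in 25 and lower in 13 of 52, or 16 over the list alone (camera adjusted p = 0.258), with acyl-CoA dehydrogenase fadE12 PCON_12882 at 3.32 and carnitine acetyltransferase PCON_06039 at −4.64 on the log2 scale. Transporters were higher in 27 and lower in 33 of 94, or 32 and 34 over the list alone (camera adjusted p = 0.58). Proteases were higher in 11 and lower in 15 of 34 (0.671) and oxidative stress genes in 17 and 16 of 50, or 17 and 17 over the list alone (0.671).

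In the same comparison MAP kinase and G protein genes were higher in 5 and lower in 9 of 18 (camera adjusted p = 0.505), and DNA replication and cell cycle genes in 31 and 34 of 101, or 32 and 34 adjusted over the list alone (0.934). Mitochondrial ribosomal proteins were higher in 13 and lower in 14 of 58 (0.517), ribosome biogenesis genes in 16 and 27 of 65 (0.836) and respiratory chain genes in 12 and 21 of 57 (0.947). Autophagy genes were higher in 8 and lower in 7 of 21 (0.947), and transposons in 2 and 2 of 9, or 1 and 1 over the list alone (0.881). Atg13 PCON_09673, atg4 PCON_03094 and atg2 PCON_04554, which act in forming autophagosomes, all fell (−4.13, −4.19 and −5.19). Median, mean and camera direction differed in sign for some lists of no call. Camera pointed up for regulators (median log2 change −0.454, mean −0.55), respiratory chain (−0.27, −0.17) and oxidative stress (−0.0311, −0.0556). It also pointed up for mating (−0.104, 0.449), DNA replication (0.0047, −0.232), chitin and glucan (0.103, −0.398), transport (0.125, −0.0772), autophagy (0.0477, −0.271) and transposons (0.129, −0.136). Camera called 10 of 30 lists at its preset correlation and 0 with the correlation estimated per list, where 3 had an unadjusted p below 0.05, and fry called 18.

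**Figure D4:**
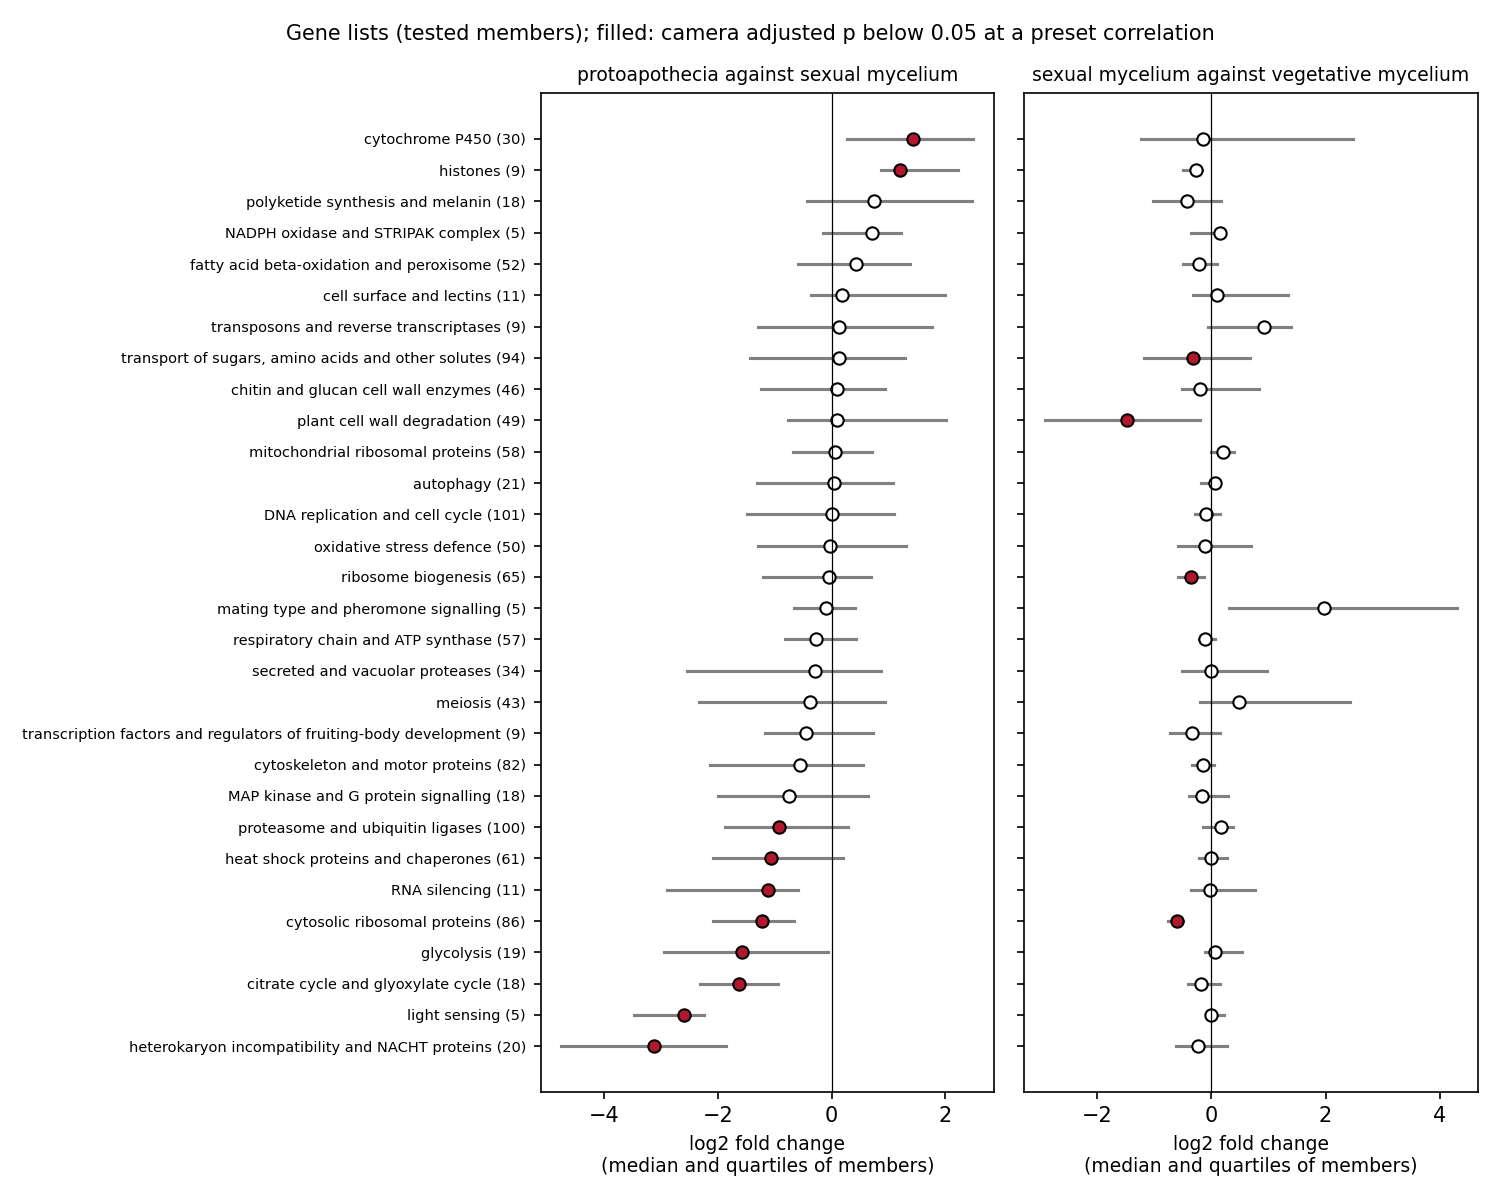
Median (point) and quartiles (line) of the log2 fold change of the tested members of each gene list (vertical axis, number of members in brackets), for protoapothecia against sexual mycelium (left) and sexual against vegetative mycelium (right). Filled points have a camera adjusted p below 0.05 at the preset correlation, 10 lists on the left from −3.13 (heterokaryon incompatibility) to 1.43 (cytochrome P450) and 4 on the right.

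Protoapothecia against vegetative mycelium set young fruiting bodies beside mycelium kept in darkness. Several genes abundant in protoapothecia had no counts in vegetative mycelium. The secreted sterol-binding protein PRY1 PCON_04545 (344.7 ± 124 CPM) was at least 3490-fold higher, cytochrome P450 52A13 PCON_02777 (268.9 ± 84) at least 2720-fold and an RCC1 and BTB domain protein PCON_11137 (228.3 ± 70.6) at least 2310-fold. Subtilisin-like protease 3 PCON_01303 reached 4738 ± 981 CPM against 0.296 ± 0.0375 (13.93, edgeR adjusted p = 4.46e-07) and the fucose-binding lectin PCON_04233 13810 ± 3430 against 9.51 ± 2.88 (10.50). MAT1-1-1 PCON_07491 rose from 26.4 ± 2.07 to 140 ± 48.4 CPM (2.40, edgeR adjusted p = 0.000123). Conidiation-specific protein 6 PCON_11571, at 652 ± 141 CPM in vegetative mycelium, had 3 counts in protoapothecia, and the NADPH oxidase PCON_03267 fell by 5.83 from 141.5 ± 15.1 CPM. In all, 4295 genes were higher and 3872 lower by edgeR at adjusted p below 0.05.

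By list, cytosolic ribosomal proteins fell in 76 of 86 members relative to vegetative mycelium, 77 adjusted over the list alone, and rose in 2 (median −2.02, camera adjusted p = 7.33e-14, adjusted p = 0.216 with an estimated correlation). Heterokaryon incompatibility genes fell in 16 of 20 and rose in 2 (−4.08, camera adjusted p = 0.00281, adjusted p = 0.216 with an estimated correlation). The citrate cycles fell in 13 of 18 and rose in 2 (−2.07, camera adjusted p = 0.00281, adjusted p = 0.303 with an estimated correlation), and glycolysis fell in 11 of 19 and rose in 1 (−1.21, camera adjusted p = 0.00395, adjusted p = 0.334 with an estimated correlation). Chaperones fell in 33 of 61 and rose in 9 (−0.976, camera adjusted p = 0.00395, adjusted p = 0.293 with an estimated correlation), and cytoskeleton genes fell in 43 of 82 and rose in 13 (−1.06, camera adjusted p = 0.00395, adjusted p = 0.216 with an estimated correlation). Light sensing genes fell in 4 of 5 (−2.52, camera adjusted p = 0.0134, adjusted p = 0.216 with an estimated correlation), in which white collar 2 PCON_05086 fell by 3.97 (edgeR adjusted p = 1.1e-06), and cryptochrome DASH PCON_04123 was not past the test (0.13, edgeR adjusted p = 0.783). RNA silencing fell in 6 of 11 and rose in 2 (−1.64, camera adjusted p = 0.0173, adjusted p = 0.293 with an estimated correlation), and ubiquitin ligases and proteasome genes fell in 53 of 100 and rose in 23 (−0.939, camera adjusted p = 0.0263, adjusted p = 0.334 with an estimated correlation). P450 genes rose in 19 of 30 and fell in 7 (1.74, camera adjusted p = 0.014, adjusted p = 0.216 with an estimated correlation), among them PCON_06415 (7.95), and pisatin demethylase PCON_02468, which detoxifies a pea phytoalexin, fell by 6.60. Light sensing, RNA silencing and glycolysis lay at percentiles 5.66, 5.6 and 2.81 of lists matched on length and expression, inside their central 95%. Apart from the ribosomal list, counts adjusted over the list alone were equal.

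Protoapothecia against the vegetative pool compared the same fruiting bodies with mycelium from several media and light conditions. A gene described as a fungistatic metabolite, PCON_07851, reached 3103 ± 687 CPM against 0.267 ± 0.177 (13.55, edgeR adjusted p = 6.93e-07), and subtilisin-like protease 3 PCON_01303 again rose by 13.37. The chitin-binding peritrophin-1 PCON_09947, at 46.6 ± 26.9 CPM, was at least 567-fold higher than the pool, which had no counts. Proline permease PCON_08572 rose from 51.9 ± 10.3 to 12030 ± 4430 CPM (7.86). Glycogenin-2 PCON_04451 fell by 10.69, from 728.4 ± 387 CPM, and galectin-3 PCON_06081, a sugar-binding protein, had 2 counts in protoapothecia against 175.8 ± 191. MAT1-1-1 PCON_07491 rose by 2.68 and wetA PCON_02676 by 3.57 (edgeR adjusted p = 7.16e-05 and 4.33e-06), and the NADPH oxidase PCON_03267 fell by 4.82. There were 4099 genes higher and 4049 lower.

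Against the pool, ribosomal proteins fell in 75 of 86 members with none higher (median −1.82, camera adjusted p = 1.75e-13, adjusted p = 0.221 with an estimated correlation). Glycolysis fell in 11 of 19 and rose in 2 (−1.34, camera adjusted p = 0.000453, adjusted p = 0.303 with an estimated correlation), and enolase PCON_11324 fell by 5.48 from 2729 ± 259 CPM. The citrate cycles fell in 13 of 18 and rose in 1 (−2.14, camera adjusted p = 0.000453, adjusted p = 0.282 with an estimated correlation), and chaperones fell in 36 of 61 and rose in 7, or 8 adjusted over the list alone (−1.26, camera adjusted p = 0.000453, adjusted p = 0.221 with an estimated correlation). Cytoskeleton genes fell in 47 of 82 and rose in 12 (−0.981, camera adjusted p = 0.00553, adjusted p = 0.221 with an estimated correlation), and incompatibility genes fell in 13 of 20, 14 over the list alone, and rose in 1 (−3.03, camera adjusted p = 0.00862, adjusted p = 0.221 with an estimated correlation). P450 genes rose in 19 of 30 and fell in 5 (1.63, camera adjusted p = 0.00862, adjusted p = 0.221 with an estimated correlation). Light sensing fell in 4 of 5 (−2.37, camera adjusted p = 0.0203, adjusted p = 0.221 with an estimated correlation), and white collar 2 PCON_05086 fell by 4.19. The light sensing list lay at percentile 6.32 of lists matched on length and expression, inside their central 95%. Ubiquitin ligases and proteasome genes fell in 55 of 100, 57 over the list alone, and rose in 20 (−0.822, camera adjusted p = 0.0292, adjusted p = 0.355 with an estimated correlation); without vegetative pool 2 the camera adjusted p was 0.059. Both phytoene genes rose (PCON_03423 by 4.54, PCON_03421 by 2.19) and geranylgeranyl diphosphate synthase PCON_05718 fell by 3.34.

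Many genes separated protoapothecia from every mycelium group. At edgeR adjusted p below 0.05 in each of the 3 comparisons, 2418 genes (20.5% of those tested) were higher and 2938 (24.9%) lower in protoapothecia than in each mycelium. In the test against a fold change of 2 these were 1472 and 1984. Benzoate 4-monooxygenase PCON_08024, the lectin PCON_04233 and phytoene synthase PCON_03423 were among the first, and white collar 2 PCON_05086, enolase PCON_11324, HET-E PCON_08266 and ribosomal protein L30 PCON_09052 among the second. Sexual mycelium was above each of the other groups for 617 genes (5.23%) and below each for 221 (1.87%). Independent lists of these sizes would share 399, 459, 165 and 27 genes. In 20 simulations with the same means in all 4 groups, the mean was 0, 0, 0 and 0.1. With no gene changed almost none is called, so these simulations cannot show how much overlap shared libraries give. The comparisons share the libraries of one group, so part of the excess may come from them.

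Protoapothecia and sexual mycelium departed from vegetative growth partly in the same direction. This was read from comparisons with no library in common. Of the 2423 genes higher in sexual than in vegetative mycelium, 1742 (71.9%) were also higher in protoapothecia than in the pool, where 34.8% of all genes were; independent lists would share 843, and 177 went the opposite way. Subtilisin-like protease 3 PCON_01303 and the lectin PCON_04233 were among them. Of the 1061 lower genes, 667 (62.9%) were also lower in protoapothecia (independent lists, 364; opposite, 154), conidiation-specific protein 6 PCON_11571 and the NADPH oxidase PCON_03267 among them. Exchanging the vegetative groups gave 1716 shared higher genes (849) and 609 shared lower ones (367). Pearson's r of the log2 changes across genes was 0.630 and 0.658 (Spearman's rho 0.499 and 0.493). Both log2 changes of the first pairing also followed traits of the genes. Spearman's rho with mRNA length was −0.209 for protoapothecia against the pool and −0.194 for sexual against vegetative mycelium. With mean expression it was −0.16 and −0.368. The overlap was not matched on these traits, so part of the excess over independent lists may come from them. The shared lower counts depended on single mycelium libraries. They were 346 and 309 without sexual mycelium 1, 386 and 373 without sexual mycelium 2, 379 and 402 (first pairing) without vegetative mycelium 1 and 2, and 385 and 405 (second pairing) without vegetative pool 1 and 2.

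Sexual against vegetative mycelium addressed what changes when surface cultures go through sexual development in light rather than stay vegetative in darkness. Light and sexual development differ together between these groups and cannot be told apart in this comparison. The RNA-binding meiosis regulator mei2 PCON_07771 rose from 0.328 ± 0.0831 to 193 ± 84.5 CPM (9.17, edgeR adjusted p = 9.96e-05), and RIM4 PCON_12941, an RNA-binding activator of meiosis in yeast, from 0.526 ± 0.077 to 93.8 ± 33 (7.46, edgeR adjusted p = 6.1e-05). Endochitinase PCON_11242 (190.2 ± 81.3 CPM) was at least 1920-fold higher than vegetative mycelium, which had no counts, and peritrophin-1 PCON_09947 (24 ± 3.79) at least 242-fold. The lectin PCON_04233 rose from 9.51 ± 2.88 to 4339 ± 704 CPM (8.83, edgeR adjusted p = 1.05e-05). Psi-producing oxygenase A PCON_11932, which makes oxylipins that balance sexual and asexual development in Aspergillus, fell by 5.74 to 40.1 ± 2.88 from 2144 ± 645 CPM. Conidiation-specific protein 6 PCON_11571 fell by 5.42, sterigmatocystin methyltransferase PCON_10694 fell by 6.70 and beta-glucosidase E PCON_09067 fell by 5.51.

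Between these mycelia 2423 genes were higher and 1061 lower by edgeR at adjusted p below 0.05 (3484 in all; 2273 and 2263 without vegetative mycelium 1 and 2). The split was 2951 and 1946 when only these groups were fitted, and 1916 and 482 in the test against a fold change of 2. The lower genes numbered 542 and 583 without sexual mycelium 1 and 2, and 631 and 615 without vegetative mycelium 1 and 2. Plant cell wall degradation fell in 23 of 49 members, 24 adjusted over the list alone, and rose in 2 (median −1.55, camera adjusted p = 1.48e-06, adjusted p = 0.511 with an estimated correlation), with beta-glucosidase 1B PCON_12780 at 7.30 ± 4.09 against 116.6 ± 20.7 CPM. Ribosomal proteins fell in 22 of 86, 16 over the list alone, and rose in 1 (−0.679, camera adjusted p = 1.48e-06, adjusted p = 0.511 with an estimated correlation). Transporters fell in 24 of 94, 32 over the list alone, and rose in 16 (−0.396, camera adjusted p = 0.0143, adjusted p = 0.511 with an estimated correlation), the amino acid permease PCON_03517 rising to 95.4 ± 23.2 from 0.39 ± 0.361 CPM. Ribosome biogenesis was called lower with 2 of 65 members past the test and none over the list alone (−0.436, camera adjusted p = 0.012, adjusted p = 0.74 with an estimated correlation), and fry gave an adjusted p of 0.0591. Meiosis genes were higher in 16 and lower in 3 of 43, or 18 and 3 over the list alone (camera adjusted p = 0.253), and lectins higher in 3 of 11, with 1 lower over the list alone (0.251). MAT1-1-1 PCON_07491 rose from 26.4 ± 2.07 to 104.7 ± 19.9 CPM (1.99), and the NADPH oxidase PCON_03267 fell by 4.10 (edgeR adjusted p = 0.00161 and 0.000232). Of the light sensing genes, cryptochrome DASH PCON_04123 rose by 2.37 (edgeR adjusted p = 0.0038) and white collar 2 PCON_05086 was not past the test (−0.06, edgeR adjusted p = 0.882). Phytoene dehydrogenase PCON_03421 and phytoene synthase PCON_03423 rose by 4.22 and 4.62, and carotenoid members higher numbered 2 of 3, or 3 over the list alone.

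Sexual mycelium against the vegetative pool set sexual development beside vegetative growth on several media and in light as well as darkness. Mei2 PCON_07771 rose by 9.71 from 0.234 ± 0.131 CPM and RIM4 PCON_12941 by 8.54 from 0.24 ± 0.0617 (edgeR adjusted p = 9.2e-05 and 4.22e-05). The fungistatic metabolite gene PCON_07851 rose from 0.267 ± 0.177 to 587.5 ± 6.37 CPM (11.15, edgeR adjusted p = 9.59e-06). L-amino-acid oxidase PCON_05797 fell by 6.77, to 5.53 ± 2.73 from 607.1 ± 124 CPM, asparaginase PCON_06618 fell by 6.52 and endochitinase PCON_11068 fell by 6.05 (edgeR adjusted p = 3.25e-05 for the first). MAT1-1-1 PCON_07491 rose by 2.26 and cryptochrome DASH PCON_04123 by 2.84, and no carotenoid gene passed the test (edgeR adjusted p = 0.166 for PCON_05718, 0.852 for PCON_03421 and 0.935 for PCON_03423). There were 2331 genes higher and 1117 lower, 3448 in all, with 2286 without sexual mycelium 1 and 2265 without vegetative pool 1. The split was 2657 and 1759 when only these groups were fitted, and 1829 and 543 in the test against a fold change of 2. The lower genes numbered 523 and 646 without sexual mycelium 1 and 2 and 694 without vegetative pool 1.

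Transporters formed the list with most falls against the pool, 40 of 94 lower and 12 higher, or 42 and 14 adjusted over the list alone (median −0.677, camera adjusted p = 1.96e-05, adjusted p = 0.227 with an estimated correlation). The amino acid permease AGP3 PCON_07075 fell by 4.38 to 14.9 ± 2.49 from 308.8 ± 100 CPM (edgeR adjusted p = 3.32e-05) and quinate permease PCON_03754 fell by 3.58. Ribosomal proteins were lower in 7 of 86 and in none over the list alone (−0.594, camera adjusted p = 1.81e-05, adjusted p = 0.579 with an estimated correlation). Respiratory chain genes were lower in 8 of 57, or 1 over the list alone (−0.539, camera adjusted p = 0.000406, adjusted p = 0.579 with an estimated correlation). Beta-oxidation and peroxisome genes fell in 11 of 52 and rose in 2, also over the list alone (−0.416, camera adjusted p = 0.0041, adjusted p = 0.227 with an estimated correlation), and carnitine acyltransferase PCON_02608 fell by 2.70 (edgeR adjusted p = 0.000205). Oxidative stress genes fell in 10 of 50 and rose in 5, also over the list alone (−0.399, camera adjusted p = 0.0319, adjusted p = 0.659 with an estimated correlation), superoxide dismutase 5 PCON_08184 to 217.7 ± 16.6 from 1640 ± 76.3 CPM. That call ended without sexual mycelium 1 (camera adjusted p = 0.144) or vegetative pool 2 (0.0846), and under fry (0.084). Lists called numbered 5, but 11 without sexual mycelium 2 and 8 without vegetative pool 1. Meiosis genes were higher in 14 and lower in 1 of 43, or 17 and 1 over the list alone (camera adjusted p = 0.0913).

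Vegetative mycelium against the vegetative pool compared a dark surface culture with the mixed vegetative cultures. These groups differ in light, medium, culture form and harvest days, which cannot be told apart here. Carotenoid synthesis was lower in vegetative mycelium than in the pool in 3 of 3 members, also over the list alone. Phytoene dehydrogenase PCON_03421 fell by 4.07, to 17 ± 8.99 from 285.2 ± 126 CPM (edgeR adjusted p = 0.00361). Without vegetative mycelium 1 the edgeR adjusted p of phytoene synthase PCON_03423 was 0.0708. That of geranylgeranyl diphosphate synthase PCON_05718 was 0.222 there and 0.0534 to 0.132 without any one of the other mycelium libraries. The lectin PCON_04233 fell by 4.64 to 9.51 ± 2.88 from 238.1 ± 31.6 CPM and an ammonium transporter PCON_08415 fell by 7.67 to 4.90 ± 3.55 from 998.7 ± 110 (edgeR adjusted p = 0.000667 and 0.000814). Cellobiose dehydrogenase PCON_04062 rose from 3.23 ± 0.698 to 120.8 ± 58.9 CPM (5.23, edgeR adjusted p = 0.00313) and beta-glucosidase F PCON_11263 from 59.6 ± 5.55 to 319.9 ± 62.2 (2.43, edgeR adjusted p = 0.002). WetA PCON_02676 rose by 2.30. This comparison had the fewest calls and rested most on single libraries, with 211 genes higher and 402 lower (613 in all). The split was 823 and 812 when only these groups were fitted, 506 and 727 by DESeq2, 113 and 235 with a replicate block and 46 and 130 in the test against a fold change of 2. The total was 84 without vegetative mycelium 1, 113 without vegetative mycelium 2, 191 without vegetative pool 1 and 408 without vegetative pool 2, and 360 and 368 without sexual mycelium 1 and 2, which enter through the shared estimate of spread. The higher genes numbered 374 without protoapothecia B, which enters in the same way.

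Between the vegetative groups, plant cell wall degradation rose in 11 of 49 members and fell in 1, or 20 and 5 adjusted over the list alone (median 0.879, camera adjusted p = 3.25e-06, adjusted p = 0.466 with an estimated correlation), and fry gave 0.0724. Lectins fell in 5 of 11 and rose in 1 (−0.568, camera adjusted p = 0.00173, adjusted p = 0.329 with an estimated correlation). Proteases fell in 6 of 34, 7 over the list alone, and rose in 1 (−0.265, camera adjusted p = 0.00568, adjusted p = 0.378 with an estimated correlation). The extracellular metalloproteinase mep PCON_13505 fell by 3.03 and metallocarboxypeptidase A PCON_13491 fell by 3.05. Respiratory chain genes were called lower with 1 of 57 past the test and none over the list alone (−0.346, camera adjusted p = 0.000369, adjusted p = 0.466 with an estimated correlation). Transporters fell in 17 of 94 and rose in 9, or 23 and 10 over the list alone (−0.201, camera adjusted p = 0.0214, adjusted p = 0.466 with an estimated correlation; camera adjusted p = 0.145 without vegetative mycelium 1), and purine permease PCON_08423 fell by 4.87. Mitochondrial ribosomal proteins were called lower with 1 of 58 past the test, YMR-31 PCON_03818 (−0.338, camera adjusted p = 0.0266, adjusted p = 0.872 with an estimated correlation); the camera adjusted p was 0.11 without vegetative mycelium 1 and 0.364 without vegetative pool 2, and fry gave 0.185. RNA silencing was called higher with 1 of 11 past the test, or 3 over the list alone (0.465, camera adjusted p = 0.0167, adjusted p = 0.466 with an estimated correlation), but at 0.0781 without vegetative pool 2 and 0.092 under fry.

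The authors' deposited table also holds their own consensus calls for the same comparisons. Against sexual mycelium the authors' deposited table called 1958 genes higher and 3743 lower in protoapothecia, and 97.8% of its calls among the genes tested here had the same call by edgeR. The share was 97.8% against vegetative mycelium and 98.5% against the pool, 84.2% and 86.2% for sexual mycelium against vegetative mycelium and the pool, and 46.8% between the vegetative groups, where the authors' deposited table called 459 genes higher and 838 lower. No gene was called in opposite directions. The share in the other direction was lower against sexual mycelium. Of the 3146 higher and 4071 lower genes by edgeR there, 1834 and 3428 were also called so by the authors' deposited table.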

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

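No test in this part was chosen after its result was seen. Total counts of changed genes in the 3 protoapothecium comparisons stayed within 1.5 times of the values reported under each alternative run, and no gene was called in opposite directions in any of them. Without 1 library at a time they ran from 5496 to 7542 against sexual mycelium, from 6738 to 8492 against vegetative mycelium and from 6794 to 8471 against the pool. The ranges were 2263 to 4276 for sexual against vegetative mycelium, 2265 to 4239 against the pool, 84 to 875 between the vegetative groups (613 as reported), 1836 to 2735 and 2519 to 2986 for genes above and below each mycelium, and 1270 to 1932 and 1279 to 1900 for shared higher genes. Shared lower genes ranged from 346 to 933 and from 309 to 880. Fewer libraries leave less to estimate the spread from. In each of the 6 comparisons the highest count of changed genes, above that of the full fit, came without protoapothecia B, the smallest library. The cause was not tested. Leaving out a library can leave a group with 1 sample, which is then assumed to vary like the others. At adjusted p below 0.01, counts fell to 2255, 2134 and 140 genes for the 3 mycelium comparisons in the order of the report, and to 1149, 347, 1116 and 311 shared genes, as a stricter threshold must give. Against a fold change of 2, 1979 genes in place of 3146 were higher in protoapothecia than in sexual mycelium, 176 genes passed between the vegetative groups, 1472 in place of 2418 were above each mycelium, and 277 and 262 were shared lower. Between the vegetative groups DESeq2 called 1233 genes and a fit of only these groups 1635, with 50.3% of them higher in place of 34.4%; the cause was not tested. A replicate block left 348 genes there and changed no list call. Replicate numbers in the labels are shared only by the mycelia, and the correlation of same-numbered deviations was 0.119, −0.157 and −0.0431, so the samples share only a number. With an estimated correlation 0 lists were called in each comparison, where 3, 5, 6, 2, 2 and 2 had an unadjusted p below 0.05. Fry called 18, 18, 22, 12, 10 and 5 lists, and it tests each list alone. Lists called without 1 library ranged from 4 to 11 for sexual mycelium against the pool (11 without sexual mycelium 2, 8 without vegetative pool 1). RLE scaling kept 45 of 45 list calls. Of 710 results for single genes eligible to be named, 698 kept their call under RLE, 694 under upper-quartile scaling, 675 of 704 under DESeq2 and 652 to 693 without 1 library. A single gene reversed: the striatin PCON_03897, at 1.22 on the log2 scale (edgeR adjusted p = 0.342) in protoapothecia against sexual mycelium, stood at −1.36, −1.21 and −1.26 against sexual mycelium, vegetative mycelium and the pool without protoapothecia C, which alone held the high counts, and at 1.74, 1.90 and 1.84 without A, the highest values without 1 library. Depth limits genes at low levels: with at least 5 counts in place of 1, protoapothecia B showed 9551 genes and A 11392.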

Other observations

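The fixed-share test below was written after its values were seen, and the tests of neighbours, domains, set properties and length were chosen after the sets were known. The depth test was read as undecided only after its value was seen. By the rule written beforehand its result went with low depth. Genes above every mycelium in protoapothecia and genes below every mycelium had different make-ups. Among the 2418 higher genes, 35.9% had no described product, above the 27.4% (95% of draws 26 to 28.8) of sets of other genes matched on expression but close to the 35.5% of all genes tested, and 10.6% were predicted extracellular against 7.9% (6.87 to 8.98) in matched sets and 8.65% of all genes tested. Among the 2938 lower genes the shares were 19.9% against 28.6% (27.3 to 30) and 4.97% against 10% (9.02 to 11.2). Of 505 protein domains tested, 4 were enriched among the lower genes by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. Unlike the shares above, this test was not matched on expression, nor on mRNA length. Genes with the longest transcripts tended to fall in protoapothecia, so length may play a part in these calls. The fungal transcription factor domain Fungal_trans was found in 31 of its 53 genes (16.7 by chance, adjusted p = 0.0192), and the ATPase domains AAA_22 and AAA_16 and the elongation factor domain GTP_EFTU_D2 in 29 of 50, 27 of 46 and 12 of 15. Among the higher genes Fisher's exact test called no domain.

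The 617 genes highest in sexual mycelium were mostly undescribed, 67.6% against 63.7% (60.5 to 66.9) in matched sets, and 14.4% were predicted extracellular against 8.59% (6.48 to 10.9). Domains Con-6, named for a conidiation protein, and Peptidase_C14, the caspase family, were each found in 3 of 5 genes (0.118 by chance, adjusted p = 0.0317, Fisher's exact test). Some changed genes lay beside each other more often than in permuted placements, with a smaller or no excess for pairs farther apart. Genes highest in protoapothecia formed 555 neighbouring pairs (438 to 509 in 95% of permutations), lowest in protoapothecia 868 (659 to 741) and highest in sexual mycelium 69 (21 to 42). Counting pairs at least 1000 bases apart, the numbers were 247 (205 to 262), 388 (312 to 378) and 25 (8 to 23). The first then lay inside the permuted range, and the others above it but below the highest permutation (396 and 29). A run of 6 genes highest in protoapothecia, PCON_03863 to PCON_03868 with a trehalose phosphorylase among them, lay on scaffold 151 from 338986 to 358832. Another run of 6 such genes lay on scaffold 178. Runs of 8 and 7 genes lowest in protoapothecia lay on scaffolds 543 and 478. The length of runs was not set beside permutations.

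Incompatibility genes were lower in protoapothecia than in sexual mycelium, with a median log2 change of −3.13 (SE 0.61, 20 members). Length and expression argue against being the whole source: of 10000 lists matched on both, none had a median as low (percentile 0, matched median −0.677, 95% of lists −1.92 to 0.294). Depth was not decided. The 11 members with a mean of at least 10 CPM had a median of −2.3 (SE 0.894, 8 of them lower). This differs from the whole list by less than that SE but by more than the whole list's SE of 0.61. By the rule written beforehand, which used the latter, the result went with low depth. A large fall itself lowers the mean used to choose these members. Amplification of dissected RNA cannot be told apart from the tissue in this design, and both stay open and untested.

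Cytosolic ribosomal proteins were called lower in protoapothecia than in each mycelium at the preset correlation, and not with an estimated one (adjusted p = 0.297, 0.216 and 0.221 for camera). Short, highly expressed genes did not share the fall against sexual mycelium, where matched lists had a median of 0.469 (0.0134 to 1.06) and none reached −1.23 (percentile 0). The choice among scalings did not make the fall. The median against sexual mycelium was −1.04 (SE 0.118) under RLE, the setting nearest to 0, and −1.32 (SE 0.119) under upper-quartile scaling. These scalings moved the log2 changes of all genes by a median of only 0.168 and −0.109. They could not have brought the list to 0, so a fault common to these scalings stays open. Also open are the preparation and the tissue itself, which this design does not separate.

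Genes near absent in vegetative mycelium and abundant in protoapothecia were often intermediate in sexual mycelium. Choosing genes by these extremes favours intermediate levels in any other group, so this order is not a result by itself. If the sexual mycelium held one fixed share of protoapothecium RNA, the ratio of sexual mycelium to protoapothecia would be alike over genes. Over 96 genes under 1 CPM in the 4 vegetative libraries and over 50 CPM in each protoapothecium library (65 without description), the SD of the log2 ratio was 1.57, which is 4.16 times the replicate spread of 0.377. The ratio had a median of 13.6% (quartiles 6.79 to 29.1, range 0.906 to 156), with 3 genes above protoapothecia. One fixed share is thus not enough, and protoapothecia in the sexual mycelium together with other tissue, stage or preparation differences may still contribute.

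The log2 change was weakly correlated with mRNA length across genes, in comparisons with protoapothecia and also between sexual and vegetative mycelium. For protoapothecia against vegetative mycelium its median was 1.16 in the lowest quartile of mRNA length (median 607 bases). In the highest quartile (median 2793 bases) it was −0.601. Spearman's rho across genes was −0.235. Against sexual mycelium the same medians were 0.0197 and −0.605, with a rho of −0.117. Between the vegetative groups rho was 0.089, and for sexual against vegetative mycelium −0.194. The log2 change also followed mean expression, with a rho of −0.189 for protoapothecia against vegetative mycelium, 0.111 against sexual mycelium and −0.368 for sexual against vegetative mycelium, and the trends were not separated.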
